A study of Helianthus annuus with 24 samples.

How the data were processed

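RNA of floral nectaries from 7 sunflower lines and of leaf was sequenced in 24 libraries, 3 in each of 8 groups. Per the labels, each nectary library came from about 50 nectaries dissected over several days, 4 to 8 h after dawn, from florets of plants about 40 days old grown in a greenhouse with 16 h of light at 23 °C. Libraries were made with TruSeq RNA v2 and sequenced as 50-base paired ends on an Illumina HiSeq in 2 lanes, and 330 M reads are reported, per the labels' protocols. The deposited values are a normalized expression score, upper-quartile normalized and rounded to whole numbers, per the file headers. The read aligner, the assembly of the 42063 contigs and the counting tool are not given in the sources used here. The upper quartile of the values above 0 was 201 in each library except replicate 3 of ER, where it was 201.25 and the header does not name the normalization. Arabidopsis matches (18797 contigs, 10035 distinct genes, 44.7%) and UniRef matches (46.3%) were taken from the deposited table. Its 16 columns of group means and SDs were not used, and the table holds no sequences or lengths, so the reference gene table could not be joined and was not used here.

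The value of 1 read was estimated from the spacing of the low values, and the method recovered it with a largest error of 0.083% in 12 simulated libraries. It gave 8.45 to 16.09 M reads per library (median 12.26) and 0.678 to 1.5 units per read, with normalized totals of 10.46 to 16.97 M. Because the deposited values are normalized and rounded, they were not modelled as counts. Values were taken as log2(value + 1), contigs with a mean of at least 10 over the libraries of the fit were kept, and limma 3.58.1 in R 4.3.3 fitted 1 mean per group with moderated variances following a trend. Contigs were called at a Benjamini-Hochberg adjusted p under 0.05. Nectary against leaf was fitted on all 24 libraries, and the comparisons among nectaries on the 21 nectary libraries, with the mean of 2 lines per class. Leaf was left out of the latter because it would widen the trend of the spread, and ER enters no class. Files were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

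In 5 simulations with 200 changed contigs each, 50 per fold, the procedure recovered 8%, 63.2%, 99.6% and 100% of 1.5-, 2-, 4- and 8-fold changes for high against low (38448 contigs, 4.7% false among those called). For nectary against leaf the procedure recovered 2.4%, 16.8%, 93.6% and 100% (39935 contigs, 14.6% false). For line 434 against 467 it recovered 2.8%, 21.6%, 97.6% and 100% (38445 contigs, 11.8% false). Every contig and library was given the same dispersion, and few contigs changed. The shares of false calls therefore do not carry over to the larger numbers called in the data.

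The samples, comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined. By that rule, the 10 largest increases and decreases per comparison (5 where the medium lines were compared) were named among called, annotated contigs whose sides did not overlap in any library and whose higher mean reached 100, with 1 contig per matched gene. Up to 4 called contigs with the largest changes were added from each list. SWEET9, CWINV4, CRC, MYB21, SPS1F and SPS2F were added whatever their result, using the most abundant contig of a match. For all others the most abundant contig was taken only among those that passed, so a more abundant contig of the match may not have changed. The rule gave 239 namings of 165 contigs, of which the report gives a part. The 18 lists were nectary development and nectar secretion, sucrose synthesis and cleavage, sugar transporters, starch synthesis, starch breakdown, photosynthesis, photorespiration, jasmonate synthesis and signalling, auxin, gibberellin, floral organ and carpel regulators, pollen and tapetum markers, isoprenoid and terpene synthesis, pathogenesis-related, heat shock and wounding, circadian clock, proton pumps and aquaporins, and stomata. They were written from general knowledge of Arabidopsis genes, and the 17 with at least 3 contigs were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry were run beside it. List tests for the 2 comparisons with the medium lines were added after the data were seen.

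Alternatives tried were a larger added constant of 5, a mean of at least 50, no filter on low values, rescaling by median ratio, sample weights, the replicate number as a block, fits on the compared groups alone, 1 mean per class, the line as the unit, calls with every line of a class past every line of the other, other nectary lines against leaf, 1 contig per match in the lists, and each library left out in turn. Leaving out replicate 3 of line 452 from every comparison and summing contigs of the same match were added later. A library was called outlying within the 6 of a class by Dixon's ratio at 0.625.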

Results

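Floral nectaries of sunflower (Helianthus annuus) were profiled by RNA sequencing in 7 lines, beside leaf of 1 line. Per the labels, 6 lines were interspecific crosses classed by nectar production, with 2 lines in each class. Lines 412 and 441 were low, 452 and 456 medium, and 434 and 467 high. The other line, ER, is a maintainer line that carries no nectar class. Each of the 8 groups held 3 libraries, 24 in all. Each nectary library was made from about 50 nectaries dissected by hand from mature, secreting florets and pooled from different plants. The deposited table gives upper-quartile-normalized values, rounded to whole numbers, for 42063 assembled contigs. Of these 18797 (44.7%) carry an Arabidopsis match and are named by it here, so several contigs can bear the same gene name. From the spacing of the low values, the libraries held an estimated 8.45 to 16.09 M reads (288 M in all), and 1 read was worth 0.678 to 1.5 units. Values are the mean ± SD of these normalized values, changes are differences of log2(value + 1), and a contig was called at a Benjamini-Hochberg adjusted p under 0.05 from limma. The added 1 understates changes of contigs with low values, contigs sharing a match could split reads between them, and p-values measure the spread between pools of nectaries.

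The nectary of line 434, compared with leaf that the labels assign to the same line, held high levels of a SWEET transporter and an invertase that were scarce in leaf. SWEET9 (Helianthus17324), a sucrose uniporter required for nectar secretion in other species, stood at 135100 ± 11560 in nectary and 70.67 ± 3.512 in leaf (SD, n = 3 each; log2 change 10.88, adjusted p = 3.17e-12). CWINV2 (Helianthus23193), a cell wall invertase that splits sucrose outside the cell, stood at 186800 ± 11000 against 58.33 ± 13.65 (log2 change 11.64, adjusted p = 5.36e-16). Leaf was in turn rich in transcripts of the photosynthetic apparatus, such as the Rubisco small subunit RBCS1B (Helianthus41497) at 285900 ± 86060 in leaf and 25.67 ± 15.01 in nectary. CRC (Helianthus1659), a YABBY factor needed for nectary formation, was high in nectary (22950 ± 774.1) and low in leaf (58.33 ± 16.2).

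In this comparison 15850 of 39981 contigs tested were higher in nectary and 8778 were lower, so that 61.6% were called and 64.4% of those called were higher. The median change over all contigs was 0.48 on the log2 scale, and after each library was rescaled by its median ratio the split was 11254 higher and 12343 lower, or 47.7% higher. Relative to that shift SWEET9 changed by 10.36, CWINV2 by 11.13, SUS4 by 6.70, CRC by 8.11 and RBCS1B by -14.00. List medians were lower by about the same amount (5.50 for floral regulators, -2.02 for starch synthesis and -1.63 for isoprenoids). The labels place the leaf libraries in line 434 whereas the series text names ER as the source of leaf. Against the ER nectary in place of line 434, the counts were 16452 higher and 9958 lower. With line 434 and values summed over contigs of the same Arabidopsis match, 4380 of 10005 genes were higher and 2850 lower.

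Of 17 contigs for sucrose synthesis and cleavage, 8 rose in nectary, 6 fell and 3 did not pass (8 and 6 when adjusted over the list alone). The members that rose included the sucrose synthase SUS4 (Helianthus24021), at 37400 ± 3265 against 254.7 ± 64.05, and the invertase CWINV3 (Helianthus32544), at 10090 ± 553.4 against 66.33 ± 41.79. Helianthus13134, which matches a vacuolar invertase in Arabidopsis and a fructan fructosyltransferase in UniRef, was also higher at 5586 ± 755.6 against 45 ± 25.51 (adjusted p = 2.19e-12). SPS1F (Helianthus37345), a sucrose phosphate synthase, was at 2311 ± 293.5 in nectary and 1762 ± 169.4 in leaf and did not pass (log2 change 0.39, adjusted p = 0.123, and 0.0416 fitted on these 6 libraries alone; -0.13 after rescaling). The rules for named genes also asked for CWINV4 and SPS2F, and no contig carried either match. Among 22 sugar transporter contigs, 11 rose and 6 fell (11 and 6 adjusted over the list alone). SWEET10 (Helianthus10294) was at 71230 ± 15930 against 36.33 ± 11.68, whereas SWEET7 (Helianthus15801) was at 1329 ± 695.5 against 4.333 ± 3.786. SWEET12 (Helianthus36595), a phloem sucrose exporter of Arabidopsis leaves, was lower in nectary at 4 ± 6.928 against 810.7 ± 105.6. This does not hold for SWEET12 matches in general, since Helianthus27224 was expressed in nectaries of the high and low lines, as given below. Neither list moved as a whole in limma's camera test with a preset correlation (adjusted p = 0.601 and 0.268). With 1 contig per matched gene the sucrose list did (adjusted p = 0.00074). The contig kept was the one with the highest mean over the 24 libraries, of which 21 were nectary. This choice favours contigs that are high in nectary, so a rise is partly built into that result.

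The floral organ and carpel regulators rose, with 15 of 21 contigs higher and 3 lower (15 and 3 adjusted over the list alone, list median 5.99, camera adjusted p = 8.09e-06). AG (Helianthus13335), the MADS-box factor of stamens and carpels, was at 17060 ± 1147 against 18.67 ± 4.509. SEP1 (Helianthus30406) was at 2655 ± 130.1 against 5.333 ± 3.786, and PI (Helianthus26317) at 393.3 ± 56.08 against 0.3333 ± 0.5774. The ovule regulator STK (Helianthus29199) was among the 3 that fell, at a mean of 4.667 against 353.7 (adjusted p = 1.43e-05). In the list for nectary development and nectar secretion, 12 of 24 contigs rose and 8 fell (12 and 8 adjusted over the list alone), and camera did not call the list (adjusted p = 0.9315). MYB21 (Helianthus32958), a jasmonate-responsive factor of flower maturation, rose to 13960 ± 1116 from 10 ± 6.083 in leaf. Of the 8 that fell, 5 matched TPS21, a sesquiterpene synthase of Arabidopsis flowers, led by Helianthus28712, which was listed at 0 in the 3 nectary libraries of line 434 and averaged 4052 ± 330.5 in leaf.

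**Figure D1:**
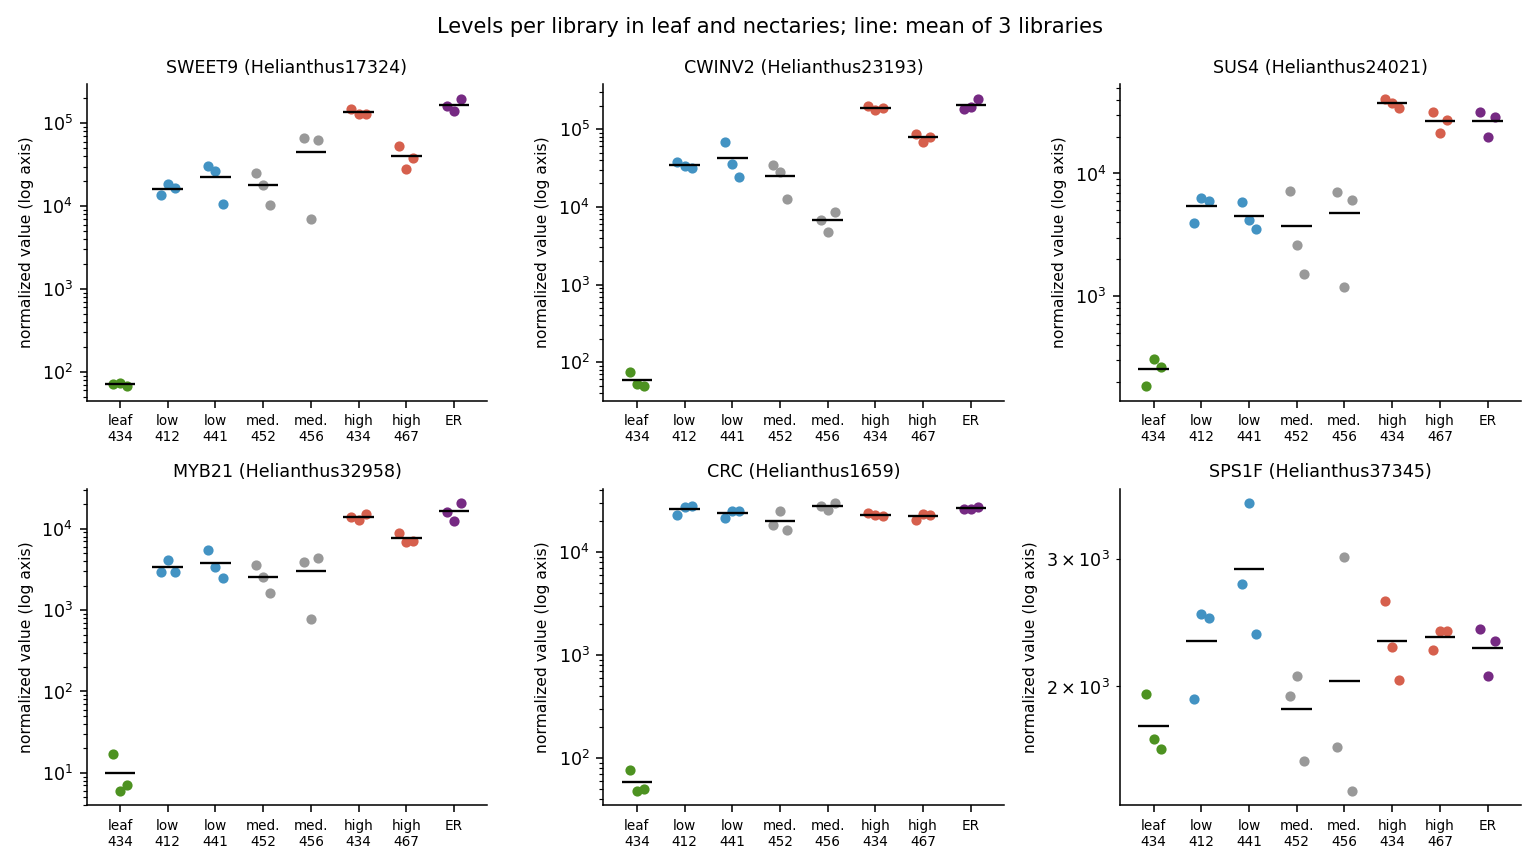
Normalized values on a log axis of 6 contigs in each of the 24 libraries (points; the bar is the mean of 3 libraries; med. is the medium class). SWEET9, CWINV2, SUS4, MYB21 and CRC lay at 311 or less in the leaf libraries and at 773 or more in the nectary libraries, and CRC stayed at group means of 19850 to 27680 across the 7 nectary lines.

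Photosynthesis and photorespiration contigs were lower in the nectary. All 73 photosynthesis contigs were lower (73 adjusted over the list alone, list median -10.42, or -10.34 with the 3 contigs listed at 0 placed at the floor of 3 reads, camera adjusted p = 3.22e-53). Examples were LHCB6 (Helianthus15248), an antenna protein, at 7.667 ± 5.508 against 69790 ± 17660, and the Calvin cycle enzyme PRK (Helianthus35151) at 1 ± 1.732 against 19580 ± 2290. Of 14 photorespiration contigs 13 fell (13 and 1 higher adjusted over the list alone, median -8.06, camera adjusted p = 5.24e-13), with the glycolate oxidase GOX1 (Helianthus39318) at 6.667 ± 5.859 against 66830 ± 6268. The 1 that rose, Helianthus16826, matched the glycine decarboxylase GLDP2 and averaged 744 against 95.33. Starch synthesis had 13 of 22 contigs lower and 4 higher (the same counts adjusted over the list alone, median -1.51, camera adjusted p = 0.0003515), but the call was lost at adjusted p = 0.237 with an estimated correlation. APL1 (Helianthus25405), a large subunit of ADP-glucose pyrophosphorylase, was at 7.333 ± 5.132 against 7590 ± 1702, and the granule-bound synthase GBSS1 (Helianthus23117) at 97.67 ± 24.7 against 5888 ± 859.5. For starch breakdown 17 of 29 were lower and 3 higher (17 and 3 adjusted over the list alone, median -0.98, camera adjusted p = 0.000264, and adjusted p = 0.128 with an estimated correlation). The beta-amylase BAM3 (Helianthus2868) was at 3.667 ± 6.351 against 705.7 ± 237.5, and BAM5 (Helianthus38309) was listed at 0 in nectary against 1894 ± 700.2.

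Isoprenoid and terpene synthesis also leaned down, with 17 of 29 contigs lower and 4 higher (18 and 5 adjusted over the list alone, median -1.11, camera adjusted p = 1.12e-05, and adjusted p = 0.151 with an estimated correlation). Within it the plastid enzymes DXR (Helianthus36609; 6.333 ± 1.528 against 59880 ± 11620) and HDR (Helianthus35120; 209.7 ± 44.12 against 8673 ± 194.7) were lower. HMGR1 (Helianthus4530), of the cytosolic mevalonate route, was higher at 1070 ± 215.6 against 135.7 ± 7.572. Another DXR match, Helianthus19289, was expressed in nectaries of the high and low lines, as given below. The photosynthesis, photorespiration and floral lists kept their calls with an estimated correlation (adjusted p = 0.00996, 0.001265 and 0.00996).

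Hormone lists went both ways. Of 47 jasmonate contigs 15 rose and 19 fell (15 and 19 adjusted over the list alone). LOX2 (Helianthus17875), a lipoxygenase of jasmonate synthesis, was at 27.67 ± 14.57 against 36800 ± 7310, and JMT (Helianthus37915), which methylates jasmonate, was listed at 0 against 175.3 ± 32.04. In the auxin list 14 of 34 rose and 8 fell (14 and 8 adjusted over the list alone), among them the auxin-conjugating GH3.3 (Helianthus20254) at 145.3 ± 38.42 against 0.3333 ± 0.5774. For gibberellin 9 of 17 rose and 4 fell (9 and 4 adjusted over the list alone), with the catabolic oxidase GA2OX2 (Helianthus39671) at 385.7 ± 23.86 against 3 ± 1.732. Proton pumps and aquaporins split 9 and 9 of 26 (9 and 9 adjusted over the list alone). The proton ATPase AHA1 (Helianthus29751) was lower at 2019 ± 263.3 against 17160 ± 1162 and the aquaporin PIP2;2 (Helianthus30447) higher at 4935 ± 1436 against 904 ± 61.59. The heat shock and wounding list had 8 of 17 higher and 3 lower (8 and 3 adjusted over the list alone), including HSP70 (Helianthus18006) at 2682 ± 518.8 against 146 ± 37.36. Of 35 circadian clock contigs 12 rose and 5 fell (12 and 3 adjusted over the list alone), among them the evening gene TOC1 (Helianthus12225) at 161.3 ± 13.65 against 30.33 ± 17.24.

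Marker lists of other tissues were small. The 6 pollen and tapetum contigs, all matches to the receptor kinases ANX1 and ANX2, had 2 higher and 2 lower (2 and 2 adjusted over the list alone), with a median of -0.28, a mean of 0.915 and an upward test direction. The 8 stomata contigs, all matches to the kinase OST1, had 2 higher and 3 lower (2 and 3 adjusted over the list alone). Both contigs of the pathogenesis-related list, matches to the chitinase PR3, were lower (2 adjusted over the list alone), with Helianthus8988 at 22.67 ± 25.58 against 713.7 ± 137.3, and this list was too short for the camera test. Camera called none of the 11 lists other than the 6 named with their calls and the untested one (0 of 11, adjusted p from 0.0942 to 0.935), although limma at an unadjusted p under 0.05 passed 34 of 47 contigs in the jasmonate list alone. Fry, which does not compare a list with other contigs, passed all of these 11 but heat shock and wounding (adjusted p from 1.33e-11 to 0.0419, and 0.0843).

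Outside the lists, annotated contigs with large increases included a plantacyanin, a blue copper protein (Helianthus36955; 18280 ± 2285 against 4.667 ± 4.163), and a pectin methylesterase inhibitor family protein (Helianthus39157; 12410 ± 350.5 against 7.333 ± 2.517). Large decreases outside the lists included carbonic anhydrase 1 (Helianthus3533; 0.3333 ± 0.5774 against 32490 ± 16480) and a photosystem I P subunit (Helianthus32259), listed at 0 against 15560 ± 3449. LHY (Helianthus18635), a morning clock gene, rose in line 434 (654 ± 211.2 against 158.3 ± 99.49, adjusted p = 0.02) but not in the mean of the 7 nectary lines, where its change was -0.16. Its call was also lost after rescaling (1.64, adjusted p = 0.0517), with the ER nectary (adjusted p = 0.0591), and without replicate 2 or 3 of leaf or replicate 1 of line 434 (adjusted p = 0.0744, 0.0664 and 0.0674).

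In the nectaries of the high nectar lines 434 and 467, several transcripts of sucrose synthesis, cleavage and export were more abundant than in the low lines 412 and 441. SUS4 (Helianthus24021) was 6.46-fold higher at 32160 ± 6951 against 4976 ± 1218 (SD, n = 6 each; adjusted p = 3.39e-05). SWEET9 (Helianthus17324) was 4.52-fold higher at 87450 ± 53270 against 19350 ± 7682 (adjusted p = 0.00199), and CWINV2 (Helianthus23193) 3.44-fold higher at 132600 ± 60010 against 38540 ± 15040 (adjusted p = 6.08e-05). MYB21 (Helianthus32958) was 3.01-fold higher at 10780 ± 3625 against 3582 ± 1094 (adjusted p = 0.00154). CRC (Helianthus1659) did not differ beyond the spread (22590 ± 1121 against 24780 ± 2337, adjusted p = 0.455), nor did SPS1F (Helianthus37345; 2325 ± 193.3 against 2608 ± 552.7, adjusted p = 0.53).

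Of 38457 contigs tested, 4718 were higher and 7265 lower in the high lines, 31.2% in all. Each class holds only 2 lines, and with the line as the unit 84 contigs were higher and 220 lower, so that 11 of the 75 named contigs called here were still called. SUS4 was among these (adjusted p = 0.0239), and SWEET9, CWINV2, MYB21 and SPS4F were not (adjusted p = 0.226, 0.299, 0.113 and 0.21). Without replicate 3 of line 452, a library of neither class that stands apart in its low values, 8394 contigs were higher and 8908 lower. With all libraries and values summed over contigs of the same match, 1962 of 9773 genes were higher and 1830 lower.

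Among 14 contigs for sucrose synthesis and cleavage 7 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.126, and 0.0233 with 1 contig per matched gene). Besides SUS4 and CWINV2 they included SPS4F (Helianthus28575), a sucrose phosphate synthase, at 10190 ± 1255 against 2057 ± 638.8. In replicate 1 of line 441 CWINV2 reached 67680, against 24300 to 38330 in the other 5 low libraries. Of 19 sugar transporter contigs 8 rose and 6 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.371). SWEET10 (Helianthus10294) was at 46510 ± 29200 against 9019 ± 7021 (adjusted p = 0.00478) and the hexose transporter STP7 (Helianthus29820) at 295.5 ± 59.92 against 107.5 ± 107.8. SWEET12 (Helianthus27224) was lower at 280.2 ± 227.5 against 2962 ± 1784 and SWEET2 (Helianthus1180) at 2.333 ± 0.8165 against 246 ± 94.17. SWEET2, a vacuolar sugar transporter in Arabidopsis roots, was also called with the line as the unit (adjusted p = 0.00912).

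Photosynthesis transcripts, already scarce in nectary, were lower still in the high lines. Of 58 contigs 37 fell and 6 rose (40 and 7 adjusted over the list alone, median -1.36, camera adjusted p = 0.000208), and the call was lost at adjusted p = 0.696 with an estimated correlation. PSBO2 (Helianthus10265), of the oxygen-evolving complex, was at 82.17 ± 58.48 against 581.8 ± 148.6, and the antenna protein LHCB4.2 (Helianthus25857) at 108.5 ± 79.66 against 935.2 ± 533.7. Rubisco activase RCA (Helianthus32271) was one of the 6 that rose (411 ± 222.2 against 43.33 ± 20.1). The summed list did not order the lines by class, at 6961 in line 434, 11290 in line 467, 10610 in line 441 and 18910 in line 412, against 2599000 in leaf. Outside the list, the 200 contigs most abundant in leaf and at least 32-fold lower in the nectary of line 434 had a median change of -0.62. Line 434 is 1 of the high lines, so this choice of contigs itself favours a fall. None of 10 photorespiration contigs was called by limma (0 adjusted over the list alone), and 5 of them had an unadjusted p under 0.05.

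Isoprenoid and terpene synthesis rose, with 13 of 22 contigs higher and 1 lower (15 and 1 adjusted over the list alone, median 0.80, camera adjusted p = 0.000244). The call was lost at adjusted p = 0.696 with an estimated correlation, and at 0.179 with 1 contig per matched gene. HDS (Helianthus27617) was at 4504 ± 672.7 against 2486 ± 153.7 and DXR (Helianthus19289) at 403.3 ± 44.33 against 201.7 ± 16.35, both enzymes of the plastid methylerythritol phosphate route. The circadian clock list rose as well, with 10 of 35 contigs higher and 1 lower (10 and 1 adjusted over the list alone, median 0.24, camera adjusted p = 0.0411, and adjusted p = 0.82 with an estimated correlation and 0.2 with 1 contig per matched gene). The largest change was in a GI contig of low level (Helianthus13505; a mean of 36, listed at 0 in the low lines), while the abundant members that rose included morning-phased MYB factors, with RVE8 (Helianthus41675) at 4904 ± 1691 against 664.8 ± 431.3 and CCA1 (Helianthus18642) at 2429 ± 1232 against 584.2 ± 231. Of 19 contigs matching morning genes 9 rose and 0 fell (median 0.49), and of 16 matching evening genes 1 rose and 1 fell (median -0.04).

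**Figure D2:**
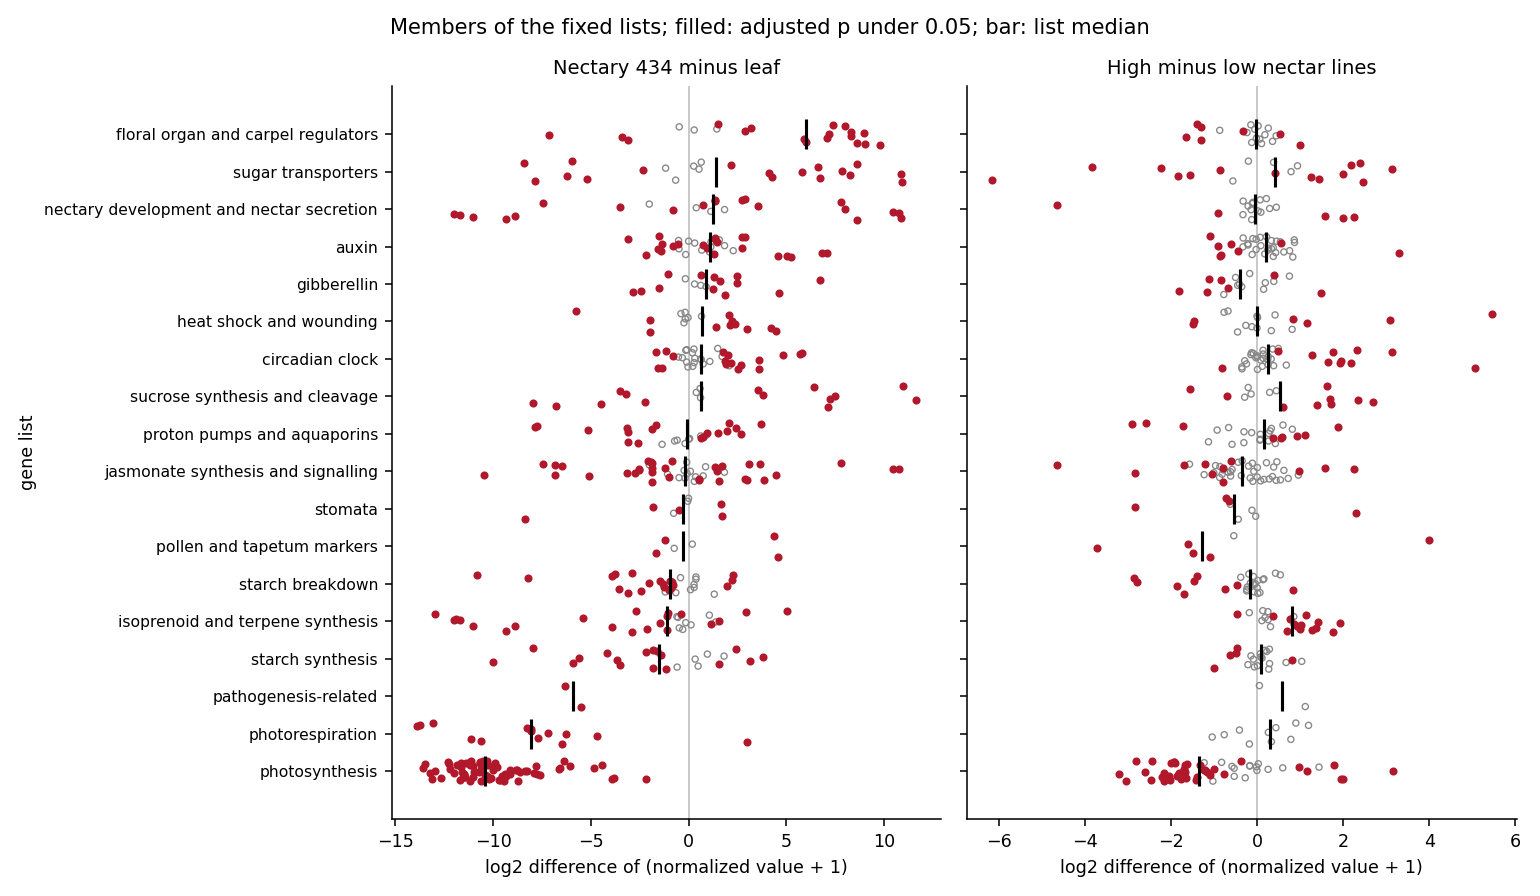
Log2 differences of the contigs in the 18 fixed lists for nectary of line 434 minus leaf and for the high minus the low nectar lines (circles, filled where the adjusted p was under 0.05; bars are list medians). The photosynthesis median was -10.42 on the left and -1.36 on the right, and the isoprenoid median changed sign from -1.11 to 0.80.

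Camera called no other list for these lines, although single members passed in most. Of the 18 contigs for nectary development and nectar secretion 3 rose and 2 fell (3 and 2 adjusted over the list alone). SWEET9 and MYB21 were higher and ARF6 (Helianthus34032), an auxin response factor of flower maturation, was lower at 655.3 ± 128.1 against 1288 ± 423.3. Its median (-0.04) and mean (-0.001) had the opposite sign to the camera test. Floral organ and carpel regulators had 2 of 20 higher and 5 lower (2 and 5 adjusted over the list alone). AG (Helianthus13335) was higher at 15300 ± 2237 against 7778 ± 1776, and both AP3 (Helianthus4961; 376.7 ± 109.8 against 970.7 ± 114.1, with 748 in replicate 1 of line 441 and 979 to 1070 in the other low libraries) and FUL (Helianthus33045; 690.5 ± 249.6 against 1639 ± 356.2) were lower. Starch synthesis had 1 of 20 higher and 4 lower and starch breakdown 1 of 27 higher and 8 lower (1 and 4, and 1 and 8, adjusted over the list alone). Those that fell included APL3 (Helianthus12451; 239.8 ± 105.8, with 450 in replicate 3 of line 467 and 173 to 234 in the other high libraries, against 457 ± 38.4) and the alpha-amylase AMY1 (Helianthus10100; 234.2 ± 127.8 against 711.2 ± 299.4). Jasmonate contigs had 3 of 45 higher and 8 lower (3 and 7 adjusted over the list alone), auxin 2 of 34 and 6 (1 and 6) and gibberellin 2 of 17 and 5 (2 and 5). Another GH3.3 contig (Helianthus20253) was at 153.2 ± 41.18 against 19.33 ± 14.18, and JAR1 (Helianthus20753), which conjugates jasmonate, at 6.167 ± 5.707 against 36 ± 6.841.

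Proton pumps and aquaporins had 6 of 26 higher and 3 lower (6 and 3 adjusted over the list alone; median 0.17, mean -0.105, upward test). The proton ATPase AHA11 (Helianthus26709) was at 150.7 ± 31.61 against 73.33 ± 30.31. Heat shock and wounding had 4 of 17 higher and 2 lower (5 and 2 adjusted over the list alone; median -0.01, mean 0.40, upward test). The small heat shock protein HSP17.6II (Helianthus33849) was lower at 80.67 ± 26.88 against 216.3 ± 25.21. Of the 6 pollen and tapetum contigs 1 rose and 4 fell (1 and 4 adjusted over the list alone). These were ANX2 (Helianthus29498), higher at 346.5 ± 122.8 against 20 ± 3.899, and others such as ANX1 (Helianthus12194), lower at 1002 ± 199.3 against 2192 ± 668.9. For stomata 1 of 8 rose and 3 fell (1 and 3 adjusted over the list alone), with OST1 (Helianthus32320) at 340.7 ± 103.6 against 521 ± 76.04. Neither pathogenesis-related contig was called by limma (0 adjusted over the list alone), and 0 had an unadjusted p under 0.05. For the 14 tested lists without a camera call the adjusted p ran from 0.126 to 0.789. Fry, which asks whether a list changed at all and not whether it changed more than other contigs, passed 5 of these 14, upward for sucrose (adjusted p = 0.00509) and downward for starch breakdown (0.00509), pollen (0.00531), stomata (0.00467) and gibberellin (0.0301). It passed the photosynthesis and isoprenoid lists (adjusted p = 0.0114 and 0.00467) and not the clock list (0.106).

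The largest class differences of annotated contigs belonged to those with low values in one class. Helianthus20665, a cytochrome P450 of family 88, was at 0.8333 ± 1.329 in the high and 796.7 ± 168.7 in the low lines, and Helianthus819, an OB-fold nucleic acid-binding protein, at 20.17 ± 5.492 against 1433 ± 121.5. In the other direction stood Helianthus8882, an EF-hand calcium-binding protein (514.7 ± 143.3 against 0.5 ± 0.8367), and Helianthus16803, a nitrate and peptide transporter family member (2532 ± 1397 against 45.17 ± 14.33). In all, 318 contigs (2.7% of those called) had a class mean under 2 on one side and of at least 50 on the other, 109 of them higher in the high lines. For 173 of the 318 this held in both lines of each class. With the line as the unit the first 3 of these 4 contigs were still called (adjusted p = 0.0334, 0.0223 and 0.0318) and Helianthus16803 was not (adjusted p = 0.0526).

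**Figure D3:**
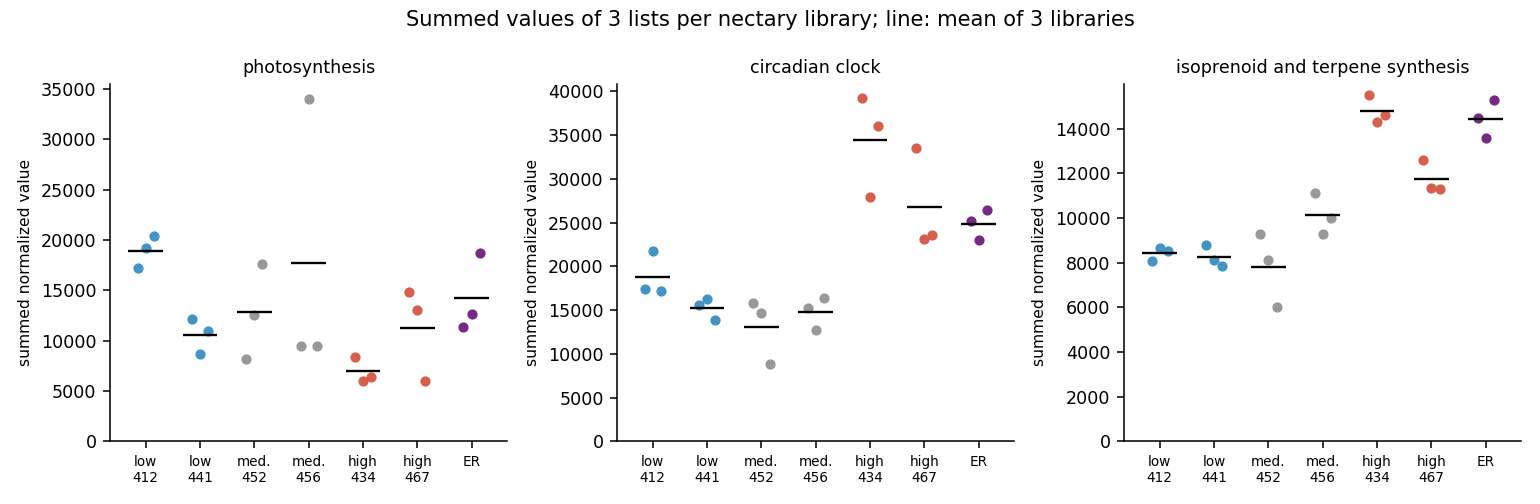
Summed normalized values of the photosynthesis, circadian clock and isoprenoid lists in each of the 21 nectary libraries (points; the bar is the mean of 3 libraries; med. is the medium class). The photosynthesis sum overlapped between classes and reached 34060 in replicate 2 of line 456, whereas the isoprenoid sum averaged 14800 and 11730 in the high lines and 8412 and 8250 in the low lines.

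The medium lines differed from the low lines in the cell wall invertase CWINV2, mainly through line 456. CWINV2 (Helianthus23193) was 2.41-fold lower in the medium lines at 15970 ± 12560 against 38540 ± 15040 (SD, n = 6 each; adjusted p = 0.000282), with line means of 6703 in line 456 and 25230 in line 452. Of the CWINV3 contigs named, Helianthus37004 was lower (143.2 ± 51.5 against 264.3 ± 47.31, adjusted p = 0.00527) and the more abundant Helianthus32544 did not pass (a mean of 2438 against 1670, adjusted p = 0.793). SWEET9 (Helianthus17324) did not pass at 31580 ± 26320 against 19350 ± 7682 (adjusted p = 0.635), but was higher without replicate 2 of line 456 (adjusted p = 0.0431). MYB21 (Helianthus32958), CRC (Helianthus1659) and SPS1F (Helianthus37345) did not pass either (adjusted p = 0.3025, 0.641 and 0.0723), although SPS1F was lower without that replicate (adjusted p = 0.00215). The chaperone HSP90.1 (Helianthus28975) was higher in the medium lines at 757.3 ± 455.7 against 219.8 ± 89.22 (adjusted p = 0.00836). Of 38457 contigs 2186 were higher and 3456 lower (14.7%). The median change was -0.15, and after rescaling by median ratio the split was 2860 and 3084, with changes of -1.45 for CWINV2 and 1.76 for HSP90.1 and a turn of sign for CRC, from -0.09 to 0.04. Among the 45 ways of setting 2 of the 6 classed lines against 2 others, this contrast ranked 26 by contigs called, high against low 5 and high against medium 1. The contrasts ranked 1, 2 and 3 (16829, 15888 and 14060 contigs) all set the high lines against line 452 and 1 other. Replicate 3 of line 452 stands apart in its low values, and its part in these ranks was not tested.

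Heat shock and wounding had 4 of 17 contigs higher and 0 lower (8 and 0 adjusted over the list alone, and 8 at an unadjusted p under 0.05 in limma; median 0.92, camera adjusted p = 0.001525), and adjusted p = 0.577 with an estimated correlation. The list sum was uneven within lines, at 42993 in replicate 1 of line 452 against 16913 and 14783 in its sister libraries. The ANX1 and ANX2 matches of the pollen list had 2 of 6 higher and 0 lower (2 and 0 adjusted over the list alone, 3 at an unadjusted p under 0.05 in limma; median 0.54, camera adjusted p = 0.0328), and adjusted p = 0.274 with an estimated correlation. In this list replicate 2 of line 456 had a sum of 4679, against 2040 to 2824 in the other 5 medium libraries. Single contigs called among the lists that camera did not call included AP1 (Helianthus21482), a floral meristem regulator, lower at 2943 ± 1061 against 5402 ± 443.5, and AHA1 (Helianthus29751), lower at 1211 ± 578.6 against 2943 ± 970.4. RBCS1B (Helianthus41497) was higher at 215.7 ± 134.3 against 63.5 ± 32.08, GOX1 (Helianthus39318) higher at 35 ± 21.66 against 6.333 ± 5.007 (both not with 1 mean per class, adjusted p = 0.0759 and 0.0614), and SWEET7 (Helianthus33780) lower at 136.3 ± 34.41 against 357 ± 111, with 70 in replicate 2 of line 456 and 136 to 169 in the other medium libraries. Helianthus819, low in the high lines as well, was at 17.33 ± 11.71 against 1433 ± 121.5.

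With the line as the unit only 1 contig was higher and 3 were lower in the medium lines, and none of the 41 named contigs called was kept, although limma passed 793 higher and 3071 lower contigs at an unadjusted p under 0.05. With 1 mean per class the counts were 667 and 1264, and without replicate 1 or replicate 2 of line 452 the lower count was 5916 or 5597. Summed over contigs of the same match, 498 of 9773 genes were higher and 590 lower.

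CWINV2, SUS4 and SWEET9 were higher in the high than in the medium lines. CWINV2 (Helianthus23193) was 8.31-fold higher in the high lines (132600 ± 60010 against 15970 ± 12560; SD, n = 6 each; adjusted p = 3.07e-08), SUS4 (Helianthus24021) 7.51-fold (32160 ± 6951 against 4282 ± 2810; adjusted p = 5.845e-06) and SWEET9 (Helianthus17324) 2.77-fold (87450 ± 53270 against 31580 ± 26320; adjusted p = 0.00656). The line means of SWEET9 overlapped between these classes, at 45400 ± 33250 in medium line 456 and 39820 ± 12410 in high line 467. Replicate 2 of line 456 was at 7069, against 66552 and 62574 in its sister libraries. The sucrose list rose, with 6 of 14 contigs higher and 1 lower (7 and 1 adjusted over the list alone, median 0.78, camera adjusted p = 0.0368, and adjusted p = 0.517 with an estimated correlation). The sugar transporters had 8 of 19 higher and 4 lower (8 and 4 adjusted over the list alone) and were not called by camera (adjusted p = 0.415). CRC (Helianthus1659) did not differ beyond the spread (22590 ± 1121 against 23760 ± 5297, adjusted p = 0.794), nor did SPS1F (Helianthus37345; adjusted p = 0.133, and 0.00819 without replicate 2 of line 456), and MYB21 (Helianthus32958) was 3.855-fold higher (adjusted p = 0.000128).

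In all 9147 contigs were higher and 7682 lower, 43.8% of those tested. The median change was 0.11, and after rescaling the split was 8491 and 8990, with CWINV2 at 3.18 and SWEET9 at 1.55. With the line as the unit 253 were higher and 301 lower, SUS4 was still called (adjusted p = 0.02), and CWINV2 and SWEET9 were not (adjusted p = 0.0781 and 0.175). Fitted on these 12 libraries alone, 5234 were higher. With values summed over contigs of the same match, 2362 of 9773 genes were higher and 1927 lower.

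Photosynthesis fell here as well (34 of 58 contigs lower and 6 higher, 36 and 7 adjusted over the list alone, median -1.24, camera adjusted p = 7.92e-05, and adjusted p = 0.752 with an estimated correlation). PSBO2 (Helianthus10265) was at 82.17 ± 58.48 against 1198 ± 1499 in the medium lines, where replicate 2 of line 456 stood at 4122 and the other 5 libraries at 1175 or less. The circadian clock list rose (16 of 35 higher and 3 lower, 18 and 4 adjusted over the list alone, median 0.865, camera adjusted p = 0.0169, and adjusted p = 0.779 with an estimated correlation), with CCA1 (Helianthus18642) at 2429 ± 1232 against 402.3 ± 301.1. Isoprenoid and terpene synthesis rose (12 of 22 higher and 2 lower, 14 and 2 adjusted over the list alone, median 0.65, camera adjusted p = 0.0169, and adjusted p = 0.752 with an estimated correlation). The OST1 matches of the stomata list fell (5 of 8 lower and 0 higher, 5 and 0 adjusted over the list alone, 5 at an unadjusted p under 0.05 in limma; median -0.795, camera adjusted p = 0.0175, and adjusted p = 0.259 with an estimated correlation). The ANX1 and ANX2 matches also fell (4 of 6 lower and 1 higher, 4 and 1 adjusted over the list alone, median -1.53, camera adjusted p = 0.0281, and adjusted p = 0.259 with an estimated correlation), with the high sum of line 456 replicate 2 (4679) on the medium side. Other called contigs were STP7 (Helianthus29820), higher at 295.5 ± 59.92 against 39.5 ± 23.24, AP1 (Helianthus21482), higher at 7002 ± 1383 against 2943 ± 1061, and the unnamed transmembrane protein Helianthus22777, lower at 2.333 ± 1.033 against 747.3 ± 180.9 and called with the line as the unit (adjusted p = 0.00414).

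CWINV2 differed between the lines of the high and of the medium class. Within the high class CWINV2 (Helianthus23193) was higher in line 434 than in line 467 (186800 ± 11000 against 78470 ± 8979, SD, n = 3 each, adjusted p = 0.0353), while SWEET9 (Helianthus17324) did not pass (135100 ± 11560 against 39820 ± 12410, adjusted p = 0.0812). Within the medium class CWINV2 was higher in line 452 than in line 456 (25230 ± 11530 against 6703 ± 1944, adjusted p = 0.00219) and SPS4F (Helianthus28575) was lower (1823 ± 1262 against 8404 ± 4851, adjusted p = 0.00329). None of the 8 sucrose and nectary contigs compared within classes differed between the low lines 412 and 441 (0 of 8 by limma, adjusted p of 0.633 or more).

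In total 3996 contigs (10.4%) differed between lines 434 and 467, 4473 (11.6%) between 452 and 456, and 2298 (6%) between 412 and 441. Without replicate 3 of line 452 the last count was 3655, and fitted on the libraries of lines 452 and 456 alone the second was 1402.

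**Figure D4:**
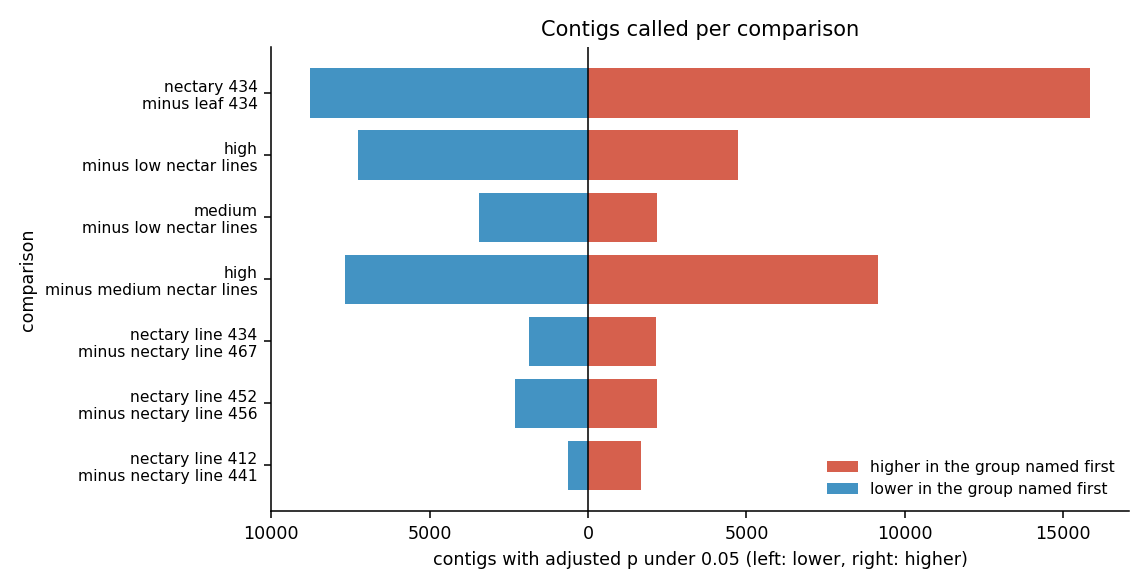
Number of contigs called at an adjusted p under 0.05 in each comparison, to the right those higher and to the left those lower in the group named first. Nectary against leaf gave 15850 higher and 8778 lower, and the comparisons within a class gave 2298 to 4473 in all.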

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

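The tests of a mixed library, of photorespiration and of abundant contigs were chosen after the results were seen, and the tests of the leaf-abundant set and of summed contigs were planned. In 180 tests of the 6 libraries of a class (21 library measures, 54 list sums and 105 named contigs), 20 found a library standing apart by Dixon's ratio. Chance gives about 1 in 20, or 9 here, so single cases carry little weight. This rate takes the 6 libraries of a class as 1 population, although they come from 2 lines.

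Line 452, of the medium class, held the libraries furthest from their class. Replicate 3 had 3903 contigs at 0 against 1448 to 2015 in the other 5 libraries, a median of 36 against 55 to 64, and 609 contigs lacking there but present in both sister libraries against 0 to 4. Its starch synthesis sum was 1775 against 2818 to 3251. The correlation of replicate 3 with its sister libraries was 0.808 and 0.836, and the cause was not tested.

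Replicate 1 of line 452 held 215 contigs that both sister libraries lacked, against 0 to 19 elsewhere in the class. RNA of 1 other line mixed into the library would bring in nearly all the contigs of that line that the sisters lack. The highest share was 78.8%, for line 441 (119 of 151 contigs, upper 95% bound 84.6%), at a median of 0.364 of its level where present, and the other lines gave 51% to 73%. Among contigs held to a level 4 times as high, 28 of 29 of line 441 (96.6%) and 24 of 26 of line 456 (92.3%) were present, so that a mixture with another line and plants of differing genotype within the pools of line 452 cannot be told apart.

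Photosynthesis contigs were lower in the high than in the low lines, at a median of -1.36. Green tissue carried over in the dissection of the low lines would also lower other leaf transcripts. The 200 most leaf-abundant contigs fell by a median of -0.62 (-0.619, spread 0.092), against -0.682 needed for 0.5 of the photosynthesis change. They were chosen for being lower in the nectary of a high line than in leaf, which itself favours a fall. This test therefore cannot decide on carry-over. Photorespiration contigs, with a median of 0.292 (spread 0.321, 5 of 10 with a mean of at least 50), argue against carry-over as the whole cause. These 10 of the list's 14 contigs passed the filter on low values. With fewer than 5 at that mean in the low lines the test would have been void, so it only just stood. The 10 most abundant contigs took at most 11.44% of a high library and at least 6.09% of a low one. For values scaled to library totals, this would let the others fall by -0.085 at most. The values here were scaled to the upper quartile, which already divides out reads taken by a few contigs. This bound therefore does not apply to them, and no conclusion is drawn from it. A difference between the lines stays open, untested.

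Contigs near 0 in the high or the low lines and expressed in the other class numbered 318, of which 173 met this in both lines of each class. Reads divided between contigs of one gene could produce such pairs where lines carry different alleles. Among 51 contigs with another contig of the same match, a median share of 0.073 of the log2 difference was left after summing, but for 0.353 of the genes the other contigs moved the opposite way, so that division of reads and a true difference cannot be told apart. For the other 267 contigs nothing could be summed without their sequences.

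Other libraries stood apart in some of the measures. In the low class, replicate 3 of line 441 had 12.21% of its total in the 10 most abundant contigs against 6.09% to 7.7%. Replicate 1 of line 441 had a sucrose list sum of 99300 against 51440 to 65600, CWINV2 (Helianthus23193) at 67680 against 24300 to 38330 and AP3 (Helianthus4961) at 748 against 979 to 1070. Replicate 1 of line 412 had a jasmonate sum of 35820 against 16210 to 22760 and a pathogenesis-related sum of 96 against 25 to 46. Replicate 2 of line 412 had 17 contigs lacking in both sisters against 0 to 5 and a proton pump and aquaporin sum of 51860 against 44380 to 47120.

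In the medium class, replicate 2 of line 456 had a photosynthesis sum of 34060 against 8225 to 17670, a pollen and tapetum sum of 4679 against 2040 to 2824 and a pathogenesis-related sum of 496 against 36 to 93. In the same library PSBO2 (Helianthus10265) was at 4122 against 1175 or less and SWEET7 (Helianthus33780) at 70 against 136 to 169. SUS4 (Helianthus24021) was at 1191 there against 7088 and 6140 in its sister libraries, and MYB21 (Helianthus32958) at 773 against 3954 and 4325. The correlation of this library with its sisters was 0.933 and 0.935, against 0.976 between those, so it differed in more than single measures. The cause was not tested. In the high class, replicate 1 of line 467 had 14 contigs lacking in both sisters against 0 to 5, and APL3 (Helianthus12451) was at 450 in replicate 3 of line 467 against 173 to 234.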

How the results depend on the processing

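Leaving out replicate 3 of line 452 from every comparison and summing contigs of the same match were chosen after the results were seen, and the other settings were planned. Counts are given as higher and lower where a comparison has both. With the line as the unit, high against low gave 84 and 220, medium against low 1 and 3, and high against medium 253 and 301. Sums per match gave 4380 and 2850 genes for nectary against leaf, 1962 and 1830 for high against low, 498 and 590 for medium against low and 2362 and 1927 for high against medium, and 959, 963 and 415 for lines 434 and 467, 452 and 456, and 412 and 441. A mean of at least 50, which tests fewer contigs, gave 5691 lower than leaf, 4759 lower in high than low, 1880 lower in medium than low, and 2432, 2872 and 1360 within classes. Sample weights gave 9219 higher in high than low, 3459 and 5354 for medium against low, and 7890, 7203 and 5740 within classes. Only the groups compared gave 8830 higher in high than low, 1450 higher in medium than low, 5234 higher in high than medium and 1402 for lines 452 and 456. One mean per class gave 667 and 1264 for medium against low. With an estimated correlation 3 of the 6 lists called for nectary against leaf were called, and 0 of the 3 for high against low by camera in limma. With 1 contig per matched gene, the contig highest on average was kept, which for nectary against leaf favours nectary. Nectary against leaf then had 7 lists called, the 6 and the sucrose list (adjusted p = 0.00074). High against low had 2, of which 1 was shared: photosynthesis was kept, the isoprenoid and circadian clock lists were lost (adjusted p = 0.179 and 0.2) and the sucrose list was gained (adjusted p = 0.0233). LHY (Helianthus18635), higher in nectary 434 than in leaf, changed by -0.157 in the mean of the 7 lines. Without 1 library the counts ran from 13553 to 15363 and 7784 to 8083 for nectary against leaf, 3936 to 4399 and 6241 to 6867 for high against low, 1696 to 2558 and 2606 to 5916 for medium against low, and 7379 to 12266 and 6768 to 8070 for high against medium. Within classes they ran from 3112 to 3326, 3293 to 5748 and 1787 to 1924. The 5916 came without replicate 1 of line 452, and without replicate 2 of that line it was 5597. Without replicate 3 of line 452, whose spread enters every comparison among nectaries, high against low gave 8394 higher and lines 412 and 441 gave 3655, and the cause was not tested. Of 218 contig counts 179 stayed within 1.5 times, 28 were weaker and 11 stronger. The weaker ones include every sum per match, where fewer genes than contigs were tested, so they do not by themselves show a loss of signal. Of 200 list results 190 were the same, 8 weaker and 2 stronger. Of 4713 values of named contigs 4415 were the same, 291 weaker, 6 stronger and 1 reversed. With the replicate number as a block the counts were 15874 and 8747 for nectary against leaf, 4705 and 7199 for high against low, 2139 and 3404 for medium against low, 9193 and 7630 for high against medium, and 3940, 4415 and 2269 within classes, none changed by 1.5 times. The numbers did not pair the samples for nectary and leaf, where correlations of deviations were 0.028 to 0.093, although all 3 pairs were best with their own number. Nor did they for high and low, at -0.16 to 0.11 with 5 of 12 best with their own. The range was wider for medium and low, at -0.287 to 0.246 with 5 of 12 best with their own, but other numbers reached 0.409. For lines 452 and 456 the highest was 0.218.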

Other observations

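The tests of the pairings of lines and of the hour of dissection were chosen after the results were seen, and the splits of libraries and the test of ER were planned.

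SWEET9 and CWINV2 reached levels in the nectary of the maintainer line ER, which has no nectar class, near those of high line 434. SWEET9 (Helianthus17324) was at 166600 ± 28650 and CWINV2 (Helianthus23193) at 207800 ± 33420 in ER (SD, n = 3), against 135100 ± 11560 and 186800 ± 11000 in line 434. MYB21 (Helianthus32958) was at 16350 ± 4028 in ER, SUS4 (Helianthus24021) at 26690 ± 6045 and SPS4F (Helianthus28575) at 10380 ± 1087.

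Averaged over the 7 nectary lines, CWINV2 ranked 6 among all contigs (83150) and SWEET9 ranked 7 (63340), and their line means spanned 6703 to 207800 and 16120 to 166600. CRC, a regulator of nectary formation, ranked 14 (24130) and SWEET10 ranked 16 (23440). Metallothionein 2B (Helianthus17329), at 112400, was more abundant than these but was also high in leaf (36960 ± 8003). Among the abundant contigs scarce in leaf were a dirigent-like protein (Helianthus36207; 21370, leaf 55.33 ± 26.01), a copper transporter (Helianthus23167; 17540, leaf 401.7 ± 195.2) and an unannotated contig (Helianthus14310; 25010, leaf 62.67 ± 18.61).

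ER may share its nectary program with the high lines. Of 11983 contigs called between high and low lines, 69.3% had an ER mean nearer to the high mean, and 71.8% of the 10193 contigs with every line of a class past every line of the other. The correlation of ER with lines 434 and 467 was 0.842 and 0.84, against 0.784 to 0.791 with the other 4 lines. Shared ancestry and a similar rate of secretion both remain open. Nectar volumes of ER, measured beside the classed lines, would show whether its secretion is similar, but a high volume would go with both.

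Of 19 contigs matching morning clock genes 9 were higher in the high lines (median 0.488, spread 0.209), and of 16 matching evening genes 1 was higher and 1 lower (median -0.044, spread 0.106). The morning set was not tested as a group, and the call of the whole clock list was lost with an estimated correlation (adjusted p = 0.82) and with 1 contig per matched gene (0.2). A candidate explanation is an earlier hour of dissection in the high lines, since nectaries were collected over 4 h of the day, and evening contigs would then be lower. Their median did not show this beyond its spread, and a few members went both ways. That spread takes contigs as independent, although the 35 clock contigs match 10 genes (estimated correlation 0.354), so it understates the uncertainty. The hour and a difference between lines cannot be told apart without collection times. Nectaries of high and low lines collected at the same hour would test it.

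The 12 libraries of 2 classes were split into 6 and 6 in 100 ways, with 1 mean per side. No other split called as many contigs as the real one (value 1 in each). Almost all other splits place sister libraries on both sides, which raises the spread within each side. The outcome was thus set by the lines, and chance is not excluded by it. These fits used the 12 libraries alone, so their counts differ from those with 1 mean per class over the 21 nectary libraries. The real split gave 13136 for high against low with 0 as the highest other, 745 with 295 for medium against low, and 7515 with 476 for high against medium. These splits break up the lines, so they do not bear on how lines were grouped. The 3 pairings of the 4 lines are too few for a share under 0.05, at 11983 with 4085 as the highest other for high against low, 5642 with 3934 for medium against low and 16829 with 4899 for high against medium. The 10 splits of 3 against 3 are likewise too few, at 26017 with 0 for nectary 434 and leaf, 5787 with 0 for lines 434 and 467, 1402 with 2 for lines 452 and 456, and 3296 with 0 for lines 412 and 441.

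Over the 45 contrasts of 2 classed lines against 2 others, the 6 with both high lines on one side gave 11593 contigs or more and the other 39 gave 10986 or fewer, with a median of 6152 over all. The high lines thus stood apart from the rest more than the low and medium lines did from each other, whose contrast ranked 26 with 5642 contigs, below that median. Since each class holds 2 lines, nectar production and descent shared by lines 434 and 467 cannot be separated here. SUS4 and SWEET2 were called between high and low lines with the line as the unit (84 higher and 220 lower contigs). SUS4 did not rise from low to medium, with means of 5430 and 4522 in lines 412 and 441 and 3758 and 4806 in lines 452 and 456. A set of more lines per class would test whether SUS4 and SWEET2 follow nectar production.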
